A study of Homo sapiens with 2 samples.

How the data were processed

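Total RNA from 2 human gastric cancer cell lines, MKN45 and its highly metastatic derivative MKN45P, was profiled on an Affymetrix exon array, 1 array per line. Per the labels' protocols, ribosomal RNA was reduced before cDNA was made with a whole-transcript kit, and the cDNA was fragmented and biotin labelled. An exon array carries several small groups of probes (probesets) along each gene, placed by exon, so that a gene is read at many places.

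The deposited values are on a log2 scale, 1 value per probeset and array, for 877986 probesets. The scale was read from the values: the highest, 13.48, would exceed what a 16-bit scanner records if it were a natural logarithm. Per the submitters' processing notes, Partek and the hg18 genome build were used; the role and version of Partek, the background correction, the summary of probes into probesets and the normalization are not given in the sources used here. Values ran from 1.42 to 13.48 in MKN45 and from 1.42 to 13.45 in MKN45P, with medians of 1.93 and 1.91 and 75th percentiles of 2.80 and 2.73. The 90th percentiles were 4.83 in MKN45 and 4.91 in MKN45P, the latter being the higher. The 2 columns therefore had close but unequal distributions, and they were used as deposited. Most probesets lay near the low end, where values are compressed, so a difference there is smaller than the difference in RNA. No detection call was used here.

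Gene symbols came from the platform annotation in GEO. Of the probesets, 286871 had exactly 1 symbol and were used, 3137 had several symbols and were left out of the gene values, and 587978 were unnamed in that annotation. The used probesets carried 18923 symbols. Of these, 15997 were current in the RefSeq table of GRCh38.p14, 2815 matched 1 current gene through an older name, 104 matched several and 7 matched none. That table served only for names, chromosomes, gene spans and gene order, and positions in hg18 were not used here.

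The difference of a gene was the median over its probesets of the MKN45P value minus the MKN45 value, in log2 units. The interquartile range of those differences and the share of probesets with the gene's sign describe the spread between probesets within these arrays. A gene counted as measured with at least 4 probesets and a median level (mean of both arrays) at or above 1.92, the median of all probesets; 13130 genes were measured, with a median of 15 probesets. With 1 array per line there is no replicate error, no test between the lines was possible and no p-value is given: every difference is between these 2 arrays, and their number limits the precision. Counts of genes past 2-fold are counts by size.

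The spread between probesets was gauged in 2 ways. Probesets of measured genes were shuffled among genes within 20 bins of level, 100 times, and the counts past 2-fold were taken again. Probesets of genes with at least 8 were also divided at random into 2 parts and each part was summarised. Gene lists fixed before the data were examined were described by the median difference of their measured members and its percentile among 10000 random lists of the same size matched on level in 20 bins; lists with fewer than 5 measured members got no percentile. Chromosome medians were set against 10000 random gene sets of the same size, drawn from all measured genes with a chromosome and not matched on level. A percentile of this kind describes these arrays and is not a significance level. The splicing index of a probeset was its difference minus that of its gene, examined in measured genes with at least 8 probesets and a gene difference under 2-fold, for probesets at or above 2.77, the 75th percentile of level. An index of at least 2 in either direction was called large.

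The genes named were chosen by a rule set before the data were examined: the 15 highest and 15 lowest measured genes with at least 75% of probesets of that sign, leaving out placeholder symbols; up to 4 members of each list with the largest differences, and every member past 2-fold where these were 10 or fewer; the 5 largest splicing indices in each direction among genes with 2 or more large probesets of the same sign, and list genes with a large probeset; and 5 genes of known alteration in gastric cancer, of which 2 are not reported here.

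The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The gene and splicing steps were tested on simulated data built from these arrays' own levels and probeset spread. The full shift was added to every probeset of a shifted gene, also near the low end, where real differences are compressed. Of 100 genes shifted by 1.5 in log2 and 100 shifted by 3, all 100 of each passed 2-fold in the right direction. Of 12930 unshifted genes 4 passed it, among 13130 genes. Of 156 probesets given an index of 4, 154 were called. The simulation checks that the steps run as intended and does not measure how many real differences they find. Alternatives were other scalings of the arrays (centring, quantile normalization, loess against level), other summaries of a gene, other filters on level and probeset number, and other thresholds.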

Results

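The data set held 1 array of MKN45, a human gastric cancer line, and 1 array of MKN45P, a highly metastatic line derived from it. Its stated comparison was between the metastatic line and its parent, at the level of genes and of exons. Across 877986 probesets the 2 arrays correlated with a Pearson r of 0.953; probesets are not independent replicates. Of 13130 measured genes, 759 (5.78%) differed 2-fold or more. There was no replicate of either line, so the spread given with each value is that between probesets of a gene within these arrays, and no difference could be tested against variation between cultures.

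MKN45P had many more genes above MKN45 than below it. In MKN45P, 602 genes were at least 2-fold higher and 157 at least 2-fold lower, so 79.3% of the genes past 2-fold were higher in the metastatic line. At 8-fold or more the counts were 28 higher and 5 lower. The median gene difference was 0.03 in log2 units over all measured genes, but it was not the same at all levels. Over the 8081 genes with a level at or above the 75th percentile it was 0.122, so genes with more signal lay slightly higher in MKN45P. Taking the difference between the lines' median levels instead gave 1263 higher and 305 lower genes. At least 75% of a gene's probesets had the gene's sign in 735 of the 759 genes. When probesets were shuffled among genes of like level, a mean of 21.5 genes passed 2-fold upward (at most 34 in 100 shuffles) and 1.21 downward (at most 4). When each gene's probesets were divided at random into 2 parts, the differences from the parts correlated across 10944 genes with a Pearson r of 0.789 and a Spearman rho of 0.756. Of 768 genes past 2-fold in the first part, 415 (54.0%) passed it the same way in the second and 20 had the opposite sign.

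**Figure D1:**
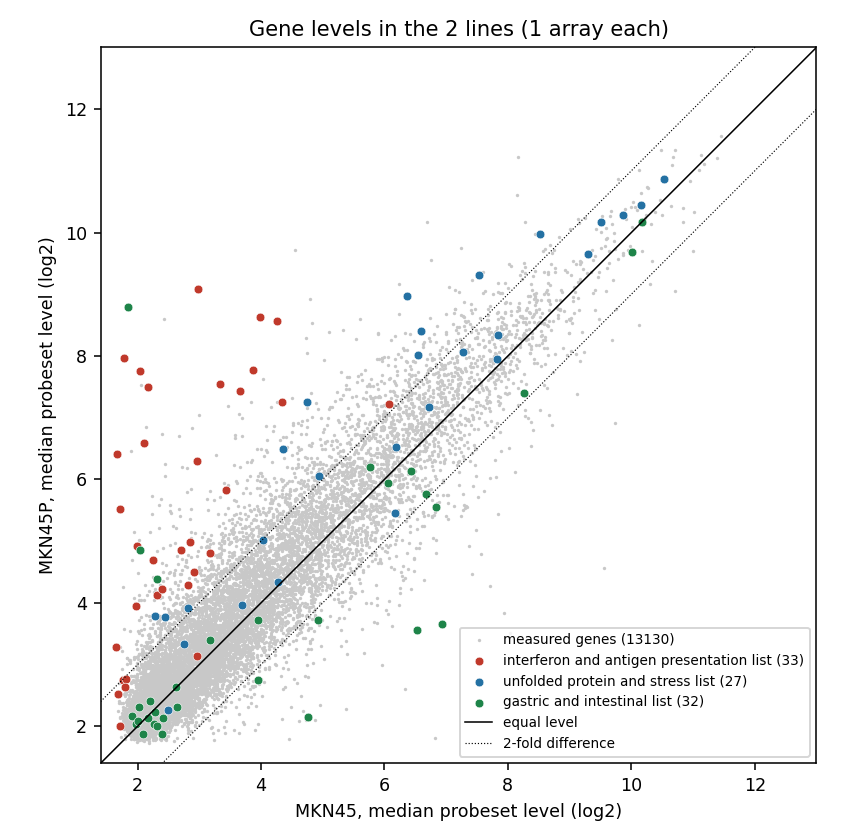
Median probeset level of each of 13130 measured genes in MKN45 (x axis, log2) and MKN45P (y axis, log2), 1 array each, with members of 3 gene lists coloured. The solid line marks equal levels and the dotted lines a 2-fold difference; all 33 members of the interferon and antigen presentation list lie on the side of MKN45P by their median probeset difference.

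The genes with the largest excess in MKN45P were mostly interferon-induced. Of the 15 highest genes, 9 belonged to the interferon and antigen presentation list: IFIT3, IFITM1, OAS2, IFI27, IFIT1, IFI35, XAF1, PSMB8 and DDX60. IFIT3, an interferon-induced antiviral gene, was higher in MKN45P by 6.07 in log2 units (interquartile range over 5 probesets 1.39 to 6.33). OAS2, a sensor enzyme for double-stranded RNA, was higher by 5.02 (3.59 to 6.04 over 25 probesets), and DDX60, a helicase of the antiviral response, by 3.77 (2.81 to 5.04 over 43 probesets, all of them higher). PSMB8, a subunit of the immunoproteasome, was higher by 4.005 (1.99 to 4.54). LCN2, which encodes the iron-siderophore carrier lipocalin 2, was higher by 6.22, with a wide range over its 9 probesets of 0.17 to 6.67. The other genes of the 15 were CEACAM6, a carcinoembryonic antigen family adhesion molecule (5.86), the lysosomal membrane gene LAMP3 (5.35), SERPING1, the C1 inhibitor of complement (5.10), SLFN5 (4.68) and IL20RB, a cytokine receptor chain (4.28). In 11 of the 15 the MKN45 level was below 2.77, the 75th percentile of all probesets, so the parental level was near the low end of the scale, the difference is compressed and the order among these genes is not determined. IFITM1, the IFIT genes and CEACAM6 have close relatives whose RNA can bind the same probes, and their values are uncertain for that reason.

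Among the genes lower in MKN45P were VSIG1 and PTGER2. VSIG1, an adhesion gene of gastric epithelium, had a difference of -5.11 in log2 units (interquartile range -5.46 to -2.46 over 12 probesets), with levels of 6.82 in MKN45 and 1.80 in MKN45P. PTGER2, a prostaglandin E2 receptor, had a difference of -4.77 (-4.93 to -4.42 over 7 probesets). The membrane mucin MUC13 (-3.02) and CDH17, the liver-intestine cadherin (-2.84), were lower at every one of their 16 and 21 probesets. So were the ion cotransporter SLC12A2 (-2.97, 32 probesets), the uroplakin UPK1B (-2.82), the transcription factor CREB3L1 (-2.75) and the surface glycoprotein CD24 (-3.22, 6 probesets). The others were LEPREL1, now named P3H2, a collagen prolyl hydroxylase (-3.47), HAVCR1 (-2.67), the retinaldehyde dehydrogenase ALDH1A1 (-2.66), AKR1C3 (-2.64), ANKS4B (-2.54), the myelin protein gene PMP22 (-2.43) and the amino acid transporter SLC7A7 (-2.41). AKR1C3 belongs to a family of near-identical genes, so its value is uncertain. In 7 of these 15 genes, VSIG1 among them, the MKN45P level was below 2.77, so the difference is compressed and their order is not determined.

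**Figure D2:**
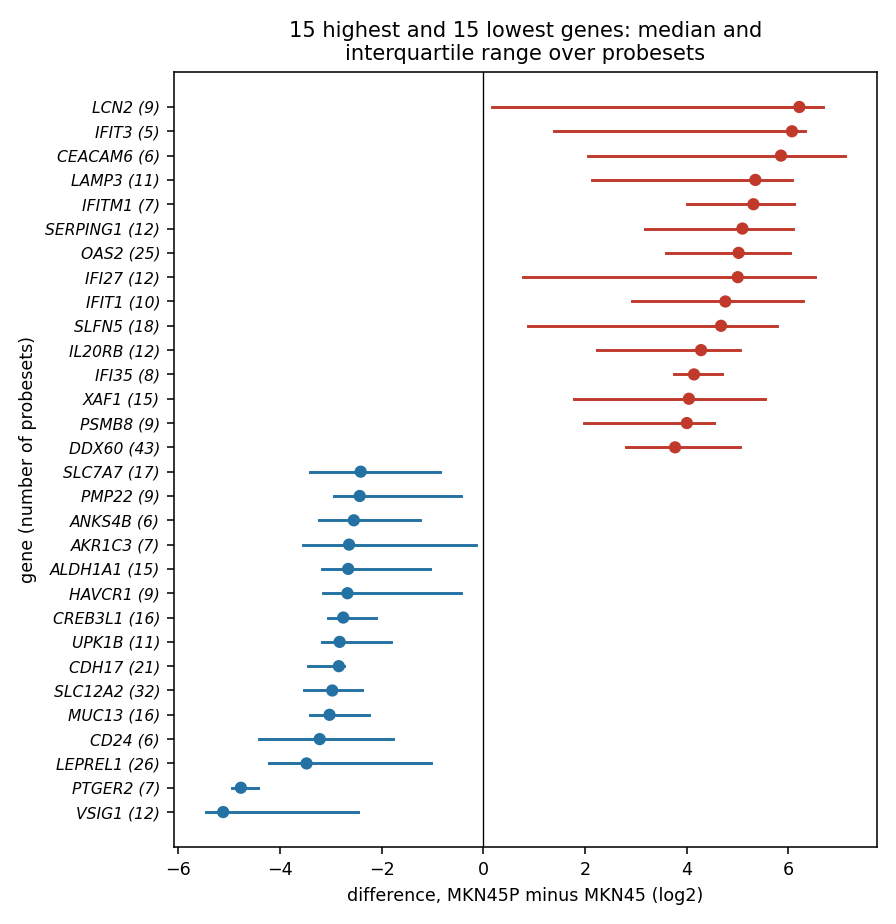
Differences (x axis, log2, MKN45P minus MKN45) of the 15 highest and 15 lowest measured genes (y axis, with the number of probesets); points are medians over probesets and lines interquartile ranges. Medians run from 3.77 for DDX60 to 6.22 for LCN2 among the higher genes and from -2.41 for SLC7A7 to -5.11 for VSIG1 among the lower ones.

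Every measured gene of the interferon response and antigen presentation list was higher in MKN45P, which does not cover genes outside the list. All 33 measured members had a positive difference; 25 were at least 2-fold higher and none was 2-fold lower. Their median difference was 2.22 in log2 units (interquartile range over members 1.03 to 3.77), above the median of each of 10000 random lists of like level, of which the central 95% ran from -0.05 to 0.28. After IFIT3, its largest values were those of IFITM1 (5.31), OAS2, IFI27 (5.01), IFIT1 (4.76), IFI35 (4.15) and XAF1 (4.05), and the smallest was 0.24. Of 7 measured markers of immune cells none was 2-fold higher, and the largest differences were NKG7 at -0.62, LYZ at -0.41, TYROBP at 0.12 and CORO1A at -0.08.

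The unfolded protein and stress response list was the other list above the central 95% of random lists. Of 27 measured members 8 were at least 2-fold higher in MKN45P and none was 2-fold lower; 25 had a positive difference. The median was 0.54 (interquartile range 0.24 to 1.17; percentile 99.9). HSPA5, the main chaperone of the endoplasmic reticulum, was higher by 1.76 (1.19 to 2.60 over 9 probesets). The sensors of unfolded protein ATF6 (1.55) and ERN1 (1.24) were higher as well, as were HERPUD1 (1.28) and DNAJB9 (1.10), which act in disposal and folding of such proteins, the transcription factor DDIT3 (1.27), TXNRD1 (1.55), a thioredoxin reductase, and VLDLR (1.402). SESN2, a stress-induced gene counted in the p53 list, was higher by 1.56. That list had 1 of 24 members 2-fold higher and 1 lower, SFN (-1.41), with CDKN1B at 0.96, GADD45A at 0.95 and a median of 0.16 (percentile 88.7).

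Genes of gastric and intestinal differentiation and of Wnt signalling and stem cells had medians below those of random lists, with small differences in most members and large ones in a few. In the differentiation list 3 of 32 measured members were 2-fold lower, MUC13, CDH17 and LGR5 (-2.38), and 3 were 2-fold higher, CEACAM6, the membrane mucin MUC4 (2.27) and ANXA10 (2.17), an annexin of gastric epithelium. The median was -0.19 (percentile 0.01). Over the main and other settings, 3 to 6 members of this list were 2-fold lower and 2 to 3 were 2-fold higher. In the Wnt and stem cell list 3 of 23 members were 2-fold lower, CD24, ALDH1A1 and LGR5, the receptor that marks intestinal stem cells. None was 2-fold higher, DKK1 was at -0.97, and the median of -0.26 lay below all 10000 random lists.

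The epithelial cadherin gene CDH1 was near the top of the scale in both lines, and the epithelial and mesenchymal lists had medians within the random range. CDH1 had levels of 10.26 in MKN45 and 10.74 in MKN45P (difference 0.55, 0.42 to 0.63 over 19 probesets). Of 28 members of the epithelial adhesion and polarity list 3 were just past 2-fold higher, the claudin CLDN7 (1.14), RBM35A, now named ESRP1, an epithelial splicing regulator (1.04), and TJP1 (1.01). With quantile normalization 1 was 2-fold higher, and with loess none was. DSP, the desmosomal plaque gene, was at -0.96, and the median was 0.19 (percentile 57.9). In the mesenchymal list 16 of 31 genes were measured, and VIM, CDH2, FN1, ZEB1, ZEB2 and SNAI2 were below the level filter. Of the 16, ITGA5 (1.94) and ACTA2 (1.23) were 2-fold higher and none was lower, with FOXC2 at -0.89, TWIST1 at -0.21 and a median of -0.04 (percentile 26.9).

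Genes of the adhesion and the receptor tyrosine kinase lists passed 2-fold in both directions, and 2 genes of the protease list were 2-fold higher. Among 36 integrin and surface adhesion genes the integrin chains ITGA5 and ITGA3 (1.41) and the surface protein CD47 (1.37) were 2-fold higher, and ITGA2 (-1.78), a collagen receptor chain, and ITGB8 (-1.36) were 2-fold lower (median -0.06, percentile 0.99). Among 30 proteases and inhibitors ADAM17, the sheddase of many surface ligands, was higher by 2.64 (2.01 to 3.06 over 23 probesets) and the kallikrein KLK6 by 2.23 (1.29 to 2.57). TMPRSS4 was at -0.99 and PLAUR at -0.74, and the median was 0.01 (percentile 30.3). Among 41 receptor tyrosine kinases and ligands the ligand EREG (2.06) and the receptors ROR1 (1.20) and MERTK (1.08) were 2-fold higher. The range was wide for EREG (0.77 to 2.68 over 8 probesets), whose median levels of 5.24 in MKN45 and 6.10 in MKN45P were less than 2-fold apart. It was also wide for MERTK (0.21 to 2.20), which was near the low end in MKN45 (1.87). FGFR4 (-1.49), IGF1R (-1.39), EGFR (-1.21) and EPHB4 (-1.02) were 2-fold lower, with a median of -0.06 (percentile 2.16). MET, the receptor for hepatocyte growth factor, was near the top of the scale in both lines, at 10.96 in MKN45 and 10.84 in MKN45P, and differed by -0.08 (-0.20 to -0.02 over 34 probesets). ERBB2 differed by -0.47 (-0.78 to -0.10). No gene of the 20 measured in the list of chemokines, cytokines and their receptors passed 2-fold; CXCL16 was at 0.88, TNFRSF21 at -0.78, TNFSF10 at 0.56 and IL6R at 0.52, and the median was -0.12 (percentile 0.55). With at least 10 probesets required per gene, that median was 0.51 over 7 genes.

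The hypoxia and glycolysis, proliferation, cholesterol synthesis, oxidative phosphorylation and ribosomal protein lists had medians within the random range, and those of drug metabolism and immediate early genes lay below it. In the hypoxia and glycolysis list P4HA1 (1.75), BNIP3L (1.49), ENO2 (1.15) and DDIT4 (1.07) were 2-fold higher among 31 genes and none was 2-fold lower (median 0.12, percentile 67.2). In the proliferation list CDC6, which loads the replicative helicase, was higher by 2.30 and RRM2 by 1.05 among 39 genes. The mitotic kinesin KIF20A was lower (-1.24), MCM4 was at -0.79 and the median was 0.16 (percentile 65.9). Cholesterol synthesis genes stayed within 2-fold in all 18 measured cases, with DHCR7 at -0.88, LSS at -0.77, SREBF2 at 0.49, EBP at -0.49 and a median of -0.03 (percentile 18.8). The same held for 25 oxidative phosphorylation genes (NDUFB5 0.86, SDHA -0.69, UQCRC1 -0.58, CYC1 -0.40; median 0.04, percentile 19.3) and 23 ribosomal protein genes (RPS2 -0.76, RPL14 -0.67, RPL35 0.59, RPS23 -0.50; median 0.01, percentile 13.3). In drug metabolism and export 4 of 20 genes were 2-fold lower, ALDH1A1, AKR1C3, the exporter ABCC2 (-1.88) and CYP2S1 (-1.60). The exporter ABCC3 (1.31) and CYP1B1 (1.15) were 2-fold higher (median -0.10, percentile 1.21; 0.11 over 15 genes with at least 10 probesets). In the immediate early list ETV5 (1.25) was 2-fold higher among 28 genes, JUN was at -0.99, DUSP4 at -0.92 and PHLDA1 at -0.86, and the median was -0.07 (percentile 1.74). Of 30 splicing regulators ESRP1 and MBNL2 (1.18) were 2-fold higher, MBNL3 was at -0.91, HNRNPA1 at 0.69 and the median was 0.17 (percentile 62.5); with loess no splicing regulator passed 2-fold upward. Only 3 replication-dependent histone genes were measured, HIST1H1C (-0.80), HIST1H2AC (-0.73) and HIST1H1E (-0.68), with a median of -0.73. HIST1H2AC was lower at 66.7% of its 6 probesets, and its median levels were close, 7.88 in MKN45 and 7.91 in MKN45P. The 3 genes are near-identical to others and their values are uncertain. Of cancer testis antigens 3 were measured, PRAME (1.07), PAGE5 (-0.46) and CTAG2 (-0.29, also the median); with so few genes the median took either sign under other settings, from -0.46 to 1.07.

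Few markers of other cell types passed 2-fold. Among 6 measured fibroblast markers FBLN1 was 2-fold higher (1.10), with ELN at -0.31, COL1A1 at 0.10, PDGFRB at -0.06 and a median of -0.05 (percentile 28.8). No endothelial marker of 8 passed 2-fold (ENG -0.30, CLDN5 -0.17, ROBO4 -0.16, CDH5 -0.09; median -0.09, percentile 9.39). The medians were -0.07 for immune markers (percentile 29.7) and 0.16 for 8 mesothelial markers (percentile 69.3), among which KRT5 (1.06) was 2-fold higher, UPK3B (-1.06) 2-fold lower, WT1 at -0.59 and CALB2 at 0.48. Of the 23 lists with a percentile, 2 lay above and 7 below the central 95% of random lists, where 1.15 would be outside by construction. Counts of members past 2-fold were small in most lists, and they moved by more than 1.5 times in 51 cases when a setting was changed.

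**Figure D3:**
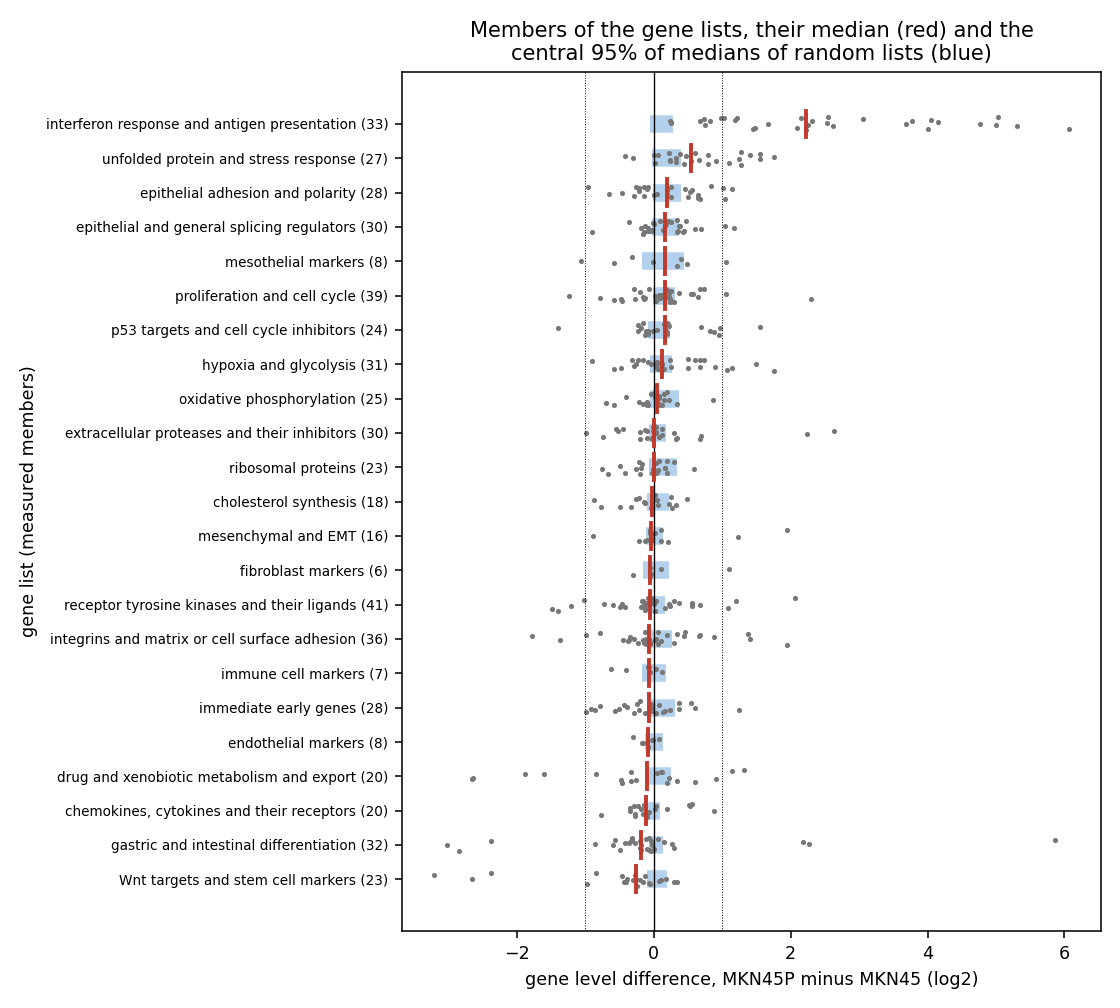
Gene differences (x axis, log2, MKN45P minus MKN45) of the measured members of each list (y axis, with the number measured); points are genes, red ticks list medians, and blue bars the central 95% of medians of 10000 random lists of like level. The interferon list has a median of 2.22, and the next highest, the unfolded protein and stress list, 0.54.

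At the exon level, single probesets departed from their gene in 1163 genes. Among 118266 probesets of 10201 genes that themselves differed less than 2-fold, 1572 (1.33%) had a splicing index of at least 2 in log2 units, 1061 of them relatively higher and 511 relatively lower in MKN45P. In 206 genes 2 or more such probesets had the same sign, 172 higher and 35 lower, with 1 gene in both counts; shuffling the marks among all examined probesets, without regard to level, gave a mean of 90.5 genes and at most 116. With the mean of a gene's probesets as its centre the count was 108. The largest positive indices were those of probeset 3318466 in TRIM22, an interferon-induced antiviral gene (6.03), 3845451 in ATP8B3 (5.94), 3272655 in KNDC1 (5.80), 2902337 in HCP5 (5.48) and 2472825 in KLHL29 (5.34). The largest negative ones were those of 2431071 in REG4, a secreted lectin of the gut (-6.19), 3778001 in KIAA0802 (-4.43), 2975023 in the kinase gene SGK1 (-3.89), 2445732 in SEC16B (-3.86) and 3136899 in TOX (-3.70).

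Several of these genes also differed 2-fold or more over all their probesets with signal, which include the large ones. Over probesets at or above the 75th percentile of level, TRIM22 was higher in MKN45P by 5.49, HCP5 by 3.96, ATP8B3 by 2.77 and KLHL29 by 1.24, and REG4 (-3.82), SGK1 (-3.48), TOX (-2.15) and KIAA0802 (-1.72) were lower. KNDC1 (0.33) and SEC16B (0.31) differed by less than 2-fold over such probesets. Of 32 examined genes known to be spliced differently in epithelial and mesenchymal cells, 7 had a large probeset. Among all 10201 examined genes 1163 had one. A gene with more probesets has more occasions for a large one, and the list was not matched on that number. The count is therefore not evidence that the list stands apart. ENAH and MBNL1 had 2 large probesets each. The indices were 2.69 and 2.29 in ENAH, an actin regulator, 2.496 and 2.03 in the splicing factor gene MBNL1, 2.52 in ITGA6, 2.05 in the hyaluronan receptor CD44, -2.30 in FGFR1, -2.10 in PKM2, now named PKM, and -2.02 in TCF7L2. Over all their probesets ITGA6 (0.03) and CD44 (-0.13) differed little. Over their probesets with signal ENAH differed by 1.13 and FGFR1 by -1.23, in the direction of their indices. The other list genes differed by less than 2-fold over such probesets. MBNL1 (0.31), ITGA6 (0.05) and PKM2 (-0.54) did so in the direction of their indices, TCF7L2 (0.58) and CD44 (-0.24) against it. Each index rests on 1 probeset of 1 array per line.

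Gene differences were not spread evenly over the chromosomes. Of 23 chromosomes 7 had a median above and 6 below the central 95% of random gene sets, where 1.15 would be outside by construction. These sets were not matched on level. Chromosome 13 had the highest median, 0.26 over 216 genes, with 26 genes 2-fold higher and none 2-fold lower, followed by chromosomes 2 (0.13), 18 (0.12) and 10 (0.10). The lowest were chromosomes 19 (-0.06 over 980 genes), 21 (-0.05) and 15 (-0.05). Without a filter on level the median of chromosome 13 was 0.05 and that of chromosome 2 was 0.03.

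**Figure D4:**
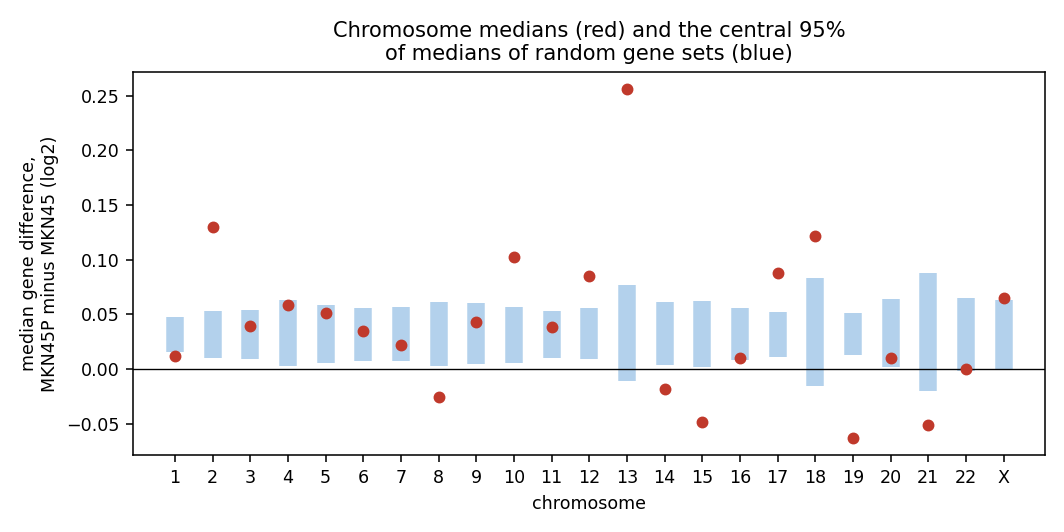
Median gene difference (y axis, log2, MKN45P minus MKN45) of the measured genes of each chromosome (x axis); red points are chromosome medians and blue bars the central 95% of medians of 10000 random gene sets of the same size. Chromosome 13, at 0.26, lies farthest above its bar.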

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

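Probesets that carried no gene symbol gave no value to the comparisons of genes, lists, exons or chromosomes above. They did count in the level cut-offs of 1.92 and 2.77, which were percentiles of all probesets. Some of them differed strongly between the arrays. Of 587978 such probesets, 220 were at least 8-fold higher in MKN45P than in MKN45, the parental line taken as control, and 122 were at least 8-fold lower. Among the 286871 probesets with 1 symbol the counts were 1428 higher and 359 lower. A level in the top 10% of all probesets was reached by 3.08% of the unnamed and 24.1% of the singly named probesets. Probesets with several symbols, also unused, included 39 that were at least 8-fold higher in MKN45P. No group of samples was large enough to look for an outlying sample.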

How the results depend on the processing

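No alternative was added after the data were seen. No paired analysis was possible because the labels give each line 1 array and share a single replicate number, and for the same reason no array could be left out. Medians by chromosome arm were not run, since the reference gave no arms. An alternative was taken as close when a count stayed within 1.5 times, a median within its 95% order-statistic interval over genes or probesets (with fewer than 6 values their full range, which covers less than 95% and makes closeness easy to reach), and a correlation or percentage within its own interval. Of 339 alternative values of main results, 300 were close, 35 moved further, and 4 reversed the sign of a list or chromosome median outside the central 95% of its random sets. None of the named genes past 2-fold changed sign under its 5 alternatives, but 19 values of named genes moved beyond their interval. The 602 higher and 157 lower genes became 1263 and 305 between the lines' median levels, 1663 and 508 at 1.5-fold, and 190 and 53 at 3-fold. Higher genes made up 73.1% (quantile normalization) to 80.9% of those past 2-fold. The interferon list median ranged from 1.88 to 2.53, its 2-fold higher members from 18 to 31, and the stress list median from 0.46 to 0.67. The mesenchymal median was -0.12 over probesets at or above the median level, and the protease median 0.083 between median levels. With at least 10 probesets per gene the chemokine median reversed to 0.51 over 7 genes and that of drug metabolism to 0.11 over 15, by construction over fewer genes. The histone median was -0.88 with loess, -0.85 with means and -0.11 with a minimum of 1 probeset. That of the cancer testis antigens, inside the full range of its 3 genes, ran from -0.46 to 1.07, the last over 1 gene with at least 10 probesets. The medians of the mesenchymal, protease, p53, cholesterol, ribosomal, oxidative phosphorylation, fibroblast and mesothelial lists, within their random ranges, also took both signs. Large splicing indices numbered 14923 at a threshold of 1, 240 at 3 and 667 at the 90th percentile of level; genes with several of the same sign numbered 2988, 28 and 57, and 108 around gene means. Divided probesets at or above the median level gave r = 0.817 and 59.6% of genes past 2-fold in both parts. Centring gave chromosome medians of 0.0302 for 1, 0.054 for 6 and, reversed, 0.0002 for 14. Without a level filter, which adds genes near the low end, chromosome 1 reversed to -0.0025. The others were then 0.026 for 2, 0.0030 for 3, 0.0066 for 4, 0.0082 for 5, 0.0065 for 6, 0.0399 for 10, 0.0007 for 11, 0.0225 for 12, 0.052 for 13, 0.038 for 17, 0.019 for 18, -0.0395 for 19 and 0.0019 for X. Except where the construction is named, the cause was not tested. Signal near the low end of the scale limits what can be seen of weakly expressed genes.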

Other observations

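The genes of this paragraph and the next were picked after their values were seen, and of the tests further on, that of the share of higher genes under other scalings, that of splicing indices on divided probesets and those of gene windows without interferon genes or adjusted for gene span were chosen after these or related results were seen. Further interferon-regulated genes outside the fixed list were higher in MKN45P: EIF2AK2, the kinase activated by double-stranded RNA, by 2.85 in log2 units, SAMHD1 by 2.92, the partners PARP9 and DTX3L by 3.05 and 3.16, PARP14 by 2.28, EPSTI1 by 2.31, PLSCR1 by 2.54, LY6E by 2.56, BTN3A1 by 2.11 and HLA-E, whose probes can bind RNA of other HLA genes, by 2.16. Stress-related genes outside the list were higher too: the mitochondrial folate enzyme gene ALDH1L2 by 2.94, NUPR1 by 2.94, WARS, a tRNA synthetase gene that interferon also induces, by 2.93, INHBE by 2.83, HSPA13 by 2.54 and GFPT1, the first enzyme of hexosamine synthesis, by 2.35. OSMR, the receptor chain for oncostatin M, was higher by 3.36, the netrin receptor UNC5B by 3.50, the serine protease PRSS8 by 3.66, the sugar transporter SLC2A10 by 3.76 and HPGD, which degrades prostaglandins, by 3.09.

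Genes lower in MKN45P included tissue factor F3 (-2.10), coagulation factor F5 (-1.87), the growth factor BMP4 (-1.94), the receptors TGFBR2 (-1.37), TNFRSF10D (-2.08), NOTCH1 (-1.21) and VDR (-1.33), the transcription factor MYB (-1.87), the kinase LYN (-1.67) and PTGS2, the inducible prostaglandin synthase (-1.68). The brush border genes MYO1A (-1.92) and ANKS4B (-2.54) were lower as well.

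The patterns tested here were found in these data, and what each explanation predicts was written before its test was run, except for those named at the start. The share of higher genes was at least 73.1% under 3 other scalings and 79.6% with the level filter at the 75th percentile, against 79.3%.

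The higher level of the interferon list in MKN45P was not traced to the measurement by the tests available. Of 33 measured members 28 had the 8 or more probesets needed for division into parts, which IFIT3 and IFITM1 did not. Of 20 such members past 2-fold in one random part of their probesets, 18 (90%) passed it in the other. For the members covered, that argues against spread between probesets. The lowest list median under 3 other scalings was 2.15, so overall scale or a smooth trend with level did not account for the difference. The 2 arrays had close distributions, so these scalings could move the median only a little. A bias confined to some genes was not examined. RNA from immune cells in the MKN45P sample is argued against as the source: 17 immune markers had a median difference of -0.0187, a highest difference of 0.12 and levels of at most 2.55 in MKN45P. What stays open is the condition of the single MKN45P culture, since with 1 array per line a response of that culture (to a virus, nucleic acid or medium, for example) cannot be told apart from a stable property of the line. A lasting interferon programme in the metastatic line may therefore be stated only as a hypothesis.

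Large splicing indices may in part reflect genes that differ as a whole, since probesets near the low end of the scale cannot show a difference, but the tests leave this open. Of 207 pairs of a gene and a direction with 2 or more large probesets, 123 (59.4%) differed 2-fold or more in that direction over the gene's probesets at or above the 75th percentile of level; this share decides nothing, since the large probesets are among those summarised. When such pairs were picked on one random part of these probesets and measured on the other, 33 of 75 (44.0%) differed 2-fold or more in that direction, against 10% in either direction among all 7600 genes with 3 or more probesets in the other part, and between the 50% or more that whole-gene differences as the main source would give and the 10% or less that would exclude them. Changes in exon use, probesets that bind other RNA and noise of a single array stay open, untested.

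Neighbouring genes differed together slightly more than in any of 100 random gene orders. A difference in gene copy number between the lines would give this, and so could other sources named below. The largest absolute median over 25 neighbouring measured genes was 0.72, on chromosome 3 from TMEM39A to PDIA5, where 7 genes were at least 2-fold higher, the interferon-regulated PARP9, DTX3L and PARP14 among them; 0 of 100 shuffles reached it, the highest at 0.71. With 43 interferon-regulated genes left out, the largest was 0.65, on chromosome 2 from PELI1 to TIA1. It was reached by 0 of 100 shuffles (highest 0.62), so these 43 genes are argued against as the whole cause, by a small margin. The 43 were measured members of the fixed list and genes picked after their values were seen. TRIM22 and WARS, also induced by interferon, stayed in, so the removal was incomplete and interferon-regulated genes at large stay open. Gene span alone is argued against as the whole cause, also by a small margin. After adjustment for it 1 of 100 shuffles reached the largest window median of 0.670, the highest at 0.675. That window was again the one from TMEM39A to PDIA5, with its interferon-regulated genes left in. Gene span and interferon-regulated genes were not removed together, so their joint effect stays open. The median of chromosome 13 was 0.25 after adjustment for gene span. Base composition, regulation shared by neighbours and the copy number of either line were not measured here and stay open. The shuffles of gene order were not matched on level, so neighbours of like level stay open as a source too.

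Chaperones of the endoplasmic reticulum and their regulators and genes of the amino acid response were also summarised apart. The median difference was 0.80 over 9 chaperone genes, 3 of them at least 2-fold higher, and 0.61 over 11 measured genes of the amino acid response, 3 of them at least 2-fold higher. Of these 20 genes 19 belong to the stress list itself, so the medians largely restate its difference and cannot decide between general endoplasmic reticulum stress and another cause.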
